A study of Mus musculus with 4 samples.

How the data were processed

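Each of the 4 samples was 1 two-colour hybridisation of an Agilent whole mouse genome array, with RNA of follistatin-treated C2C12 cells in Cy3 and of untreated cells in Cy5, per the labels. The labels call all 4 arrays dye swaps and define this as the treated sample in Cy3 and the control in Cy5, so no array has the opposite orientation per the labels. They call the samples biological replicates. The serum of the differentiation medium is given as 2% horse serum in the growth protocol and as 10% in the source names. Per the labels' protocols, 1 µg of RNA was mixed with a set of 10 spike-in transcripts, amplified and labelled.

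Spot intensity was measured by the authors with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes, while per the file headers replicate 4 was read with version 10.10.1.1. The deposited intensity values include the median brightness of each spot and of its local background, and processed signals that were background-subtracted and dye-normalized within each array by that software. The log10 ratio of Cy5 over Cy3 that the authors deposited, made by the same software, was read only to settle its direction. The authors' table of log2 values was matched to the scanner values by probe: each column was the log2 of the processed Cy3 over the processed Cy5 signal of its own array (slopes of 1.00, r = 1.00 to 3 digits over 41267 probes), so scale and direction are known, and no further centring had been applied. Its column medians were -0.16, 0.17, 0.13 and 0.11 for replicates 1 to 4. Per the series' design text, the authors filtered on detection flags and on a coefficient of variation under 50%, and used an unpaired t-test with Benjamini-Hochberg adjustment and a 1.6-fold minimum.

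The values were computed here with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8) in R 4.3.3. Median spot signals and median local backgrounds were background-corrected by normexp with an offset of 50 on all 45018 spots. The design written before the data were examined named mean signals, which were not used here because the median was the measure common to the 4 arrays. Ratios were normalized within each array by loess (span 0.3, 4 iterations) with control spots at weight 0. Control spots and spots that the scanner software marked as non-uniform or population outliers were left out, and 0 spots were saturated. Of the 45018 spots, 43379 were not controls, for 41174 probes. Spots of a probe were averaged. A probe was tested if it was well above background in the same channel on at least 3 of the 4 arrays, which 27017 probes were. The probe with the highest mean intensity stood for a gene, and a probe without a gene name stood for itself, giving 17863 features, 14997 of them with a gene symbol. The dim side of a ratio is compressed by the offset, so ratios of faint probes understate the change.

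Gene names came from the annotation columns of the scanner files and were updated through a RefSeq gene table of assembly GRCm38.p6, used for names alone: 27479 probes matched by accession, 6157 by symbol or synonym, 1262 kept the name in the file and 6276 had none. Probe positions are those of the scanner files, in mm9.

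The ratio against 0 was tested with lmFit and eBayes and adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. Adjusted p-values for single genes are limma's. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 28 lists. That p compares the genes of a list with all other genes and does not measure the spread of a shift over arrays. Each shift is the mean log2 ratio of a list minus that of all other genes, with its SD over the 4 arrays. Camera with an estimated correlation passed 0 lists (smallest adjusted p = 0.952). Fry, which tests whether the genes of a list move on balance one way, passed 0 (smallest adjusted p = 0.180), and its test for change in either direction passed 21. Some lists share members; the Smad2/3-responsive list has 6 genes in common with the collagen list.

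The text names the genes of a rule fixed before the data were examined. Among genes with a symbol, past the threshold, of 1 sign on all arrays and well above background in both channels on all arrays, it takes the 12 highest and the 12 lowest ratios. Where fewer than 12 pass in a direction, it takes all of them and then the genes of smallest p up to 6, said not to have passed; here these were taken from genes that met the other conditions. It adds 4 members of smallest p per list and a fixed set of pathway, muscle and reference genes. Ribosomal proteins and genes named only by an accession, clone or Riken number are named only in a list. The text gives part of these genes and summarises the others by list.

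The arrays were compared before averaging. No tested feature had an identical ratio on 2 arrays, which rules out a repeated copy of 1 scan and says nothing about shared cultures or RNA. Over 160 probes with repeated spots, the spread of the difference between replicates 2 and 3 was 9.01 times that of spot noise. For the other pairs it was 16.2 to 26.3 times, and these values do not decide whether cultures or RNA were shared. All 4 were kept as replicates because the labels call them so. Slide and scan were treated as batches, and slide 2 held 1 array. The slide was used as a random block (consensus correlation 0.113) and slide 1 was fitted alone.

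On simulated ratios with the spread of the real genes over 17837 features, the fit for follistatin against untreated recovered 43 of 100 genes changed 2-fold and 84 of 100 changed 4-fold, with 4 unchanged genes called. The simulated arrays were independent and held no dye effect, while the real replicates 2 and 3 correlated at r = 0.84. These rates therefore need not hold for the real arrays. A shift of 0.3 put into the collagen list was called, and it was the 1 list called. The simulated genes varied independently, while the correlation estimated in the real collagen list was 0.127. The run was also set to stop if another list was called, so this check does not bear on the real list calls. The alternatives covered background correction, normalization within and between arrays, filters, the probe that stands for a gene, the slide, moderation, array weights, the authors' table and t-test, fits to separate channels and leaving out each replicate. A further 3 were chosen after seeing the data: averaging replicates 2 and 3, replicates 1 and 4 alone, and correcting for base composition and intensity of the probe.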

Results

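The data collected were gene expression ratios from C2C12 cells, an established mouse myoblast line that fuses into myotubes when serum is lowered. Cells grown to 80% confluence were differentiated for 6 days, and the treated cultures received 200 ng/ml of recombinant human follistatin every 24 h. Follistatin is a secreted glycoprotein that binds activins and myostatin and keeps them from their receptors. Each of 4 replicates, biological replicates per the labels, was 1 two-colour Agilent whole mouse genome array, with follistatin-treated RNA in Cy3 and untreated RNA in Cy5 on all 4 per the labels. Replicates 1, 2 and 3 shared slide 1 and replicate 4 was on slide 2. The spots well above background made up 61.1% to 65.2% of the non-control spots in the follistatin channel and 61.4% to 69.4% in the untreated channel. Across genes, which are not independent replicates, the ratios of replicates 2 and 3 correlated at r = 0.84 (rho = 0.80). The other 5 pairs lay between 0.016 and 0.23 by r, and between 0.024 and 0.31 by rho. Every error and p with n = 4 counts replicates 2 and 3 as independent, which was not shown. The number of arrays limits the precision of every value, and because all 4 arrays had the same dye orientation, a dye effect particular to a gene adds to its ratio.

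The comparison asked which transcripts differ between differentiating myoblasts with and without follistatin. On all 4 arrays the treated cells had higher ratios for Lrp4, the agrin co-receptor of the neuromuscular junction, for Slit2, a secreted guidance protein, for C1s1, a complement protease, for Arpc1b, a subunit of the actin-nucleating Arp2/3 complex, for the matrix protease Adamts15 and for Gm4788. They had lower ratios for Fbxl7, an F-box protein, for Cebpb, a transcription factor of adipogenesis and acute-phase responses, for Lrrk1, a kinase, and for Tenm4, Heatr5a and Gdap10. These genes were chosen among those of 1 sign on all 4 arrays, so the choice itself fixed that agreement. None of these 12 genes passed the test: limma called 0 of the 17863 genes and unnamed probes tested, 0 higher and 0 lower, and 0 past the 1.6-fold minimum. The smallest adjusted p was 0.0900, shared by 86 of them. At an unadjusted p under 0.05 there were 3478, of which 1509 were higher and 1969 lower, against the 893 that chance gives with independent arrays. That count was 2019 with replicates 2 and 3 averaged and 1301 with replicates 1 and 4 alone, fits chosen after seeing the data that have fewer arrays. The sign was the same on all 4 arrays for 28.0% of the features tested, 2180 higher and 2822 lower. Chance gives 12.5% only for independent arrays, and more where arrays resemble each other as replicates 2 and 3 do. By mean ratio alone, 220 lay over 1.6-fold higher and 700 over 1.6-fold lower. Array by array, 1189 were higher and 986 lower by that much on replicate 1, 779 and 1366 on replicate 2, 1145 and 2004 on replicate 3, and 754 and 780 on replicate 4. The unpaired test of the authors' methods was run on separate channels with the reported processing and the 17863 features, without the authors' filters. It therefore does not repeat the authors' analysis. This test also called 0 after Benjamini-Hochberg adjustment, and 662 at an unadjusted p under 0.05 with a change over 1.6-fold. By that unadjusted p and fold, limma gave 766 with the reported processing and 2043 on the authors' table. Estimating a weight for each array from the data gave 2751 genes, with weights of 2.46 and 1.64 on replicates 2 and 3 against 0.534 and 0.464 on replicates 1 and 4. That count treats replicates 2 and 3 as independent, which was not shown. Fits to the separate channels gave 26 without the array as a block, which ignores the pairing of channels on an array. With the array as a random block they gave 24, but the estimated correlation within a spot was -0.00714, so the block changed little.

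Among the 6 genes with the smallest p in each direction, Heatr5a had the lowest log2 ratio of follistatin over untreated, -1.81 (SE 0.16, n = 4), followed by Fbxl7 at -1.69 (SE 0.14). Lrrk1 was at -1.10, Tenm4 at -1.04, Gdap10 at -1.04 and Cebpb at -0.88, with standard errors of 0.085 to 0.11. Arpc1b had the highest, 1.20 (SE 0.12), Gm4788 was at 1.11, Lrp4 at 1.00, Slit2 at 0.97, C1s1 at 0.86 and Adamts15 at 0.76. In mm9, the build named in the file headers, the Heatr5a probe lay on chromosome 12 from 53071505 to 53071564 and the Fbxl7 probe on chromosome 15 from 26718899 to 26718958. The Arpc1b probe lay on chromosome 5 from 145888791 to 145888850, the Lrp4 probe on chromosome 2 from 91353832 to 91353891 and the Cebpb probe on chromosome 2 from 167515847 to 167515905. Other probes of 4 of the 12 genes had the opposite sign, up to 0.14 for Heatr5a and 0.14 for Lrrk1, and down to -0.028 for Lrp4 and -0.24 for Slit2. The 3 probes of Fbxl7 lay between -1.69 and -0.65, the 3 of Tenm4 between -1.04 and -0.16, the 2 of Cebpb at -0.88 and -0.16, the 2 of C1s1 at 0.86 and 1.21 and the 2 of Gm4788 at 0.56 and 1.11. Arpc1b, Adamts15 and Gdap10 each had 1 probe.

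Of 28 gene lists fixed before the data were examined, 3 rose against all other genes by limma's camera with its preset correlation, and 0 fell. With the preset correlation, camera's p takes genes as its units and does not measure the spread of a shift over the arrays. With an estimated correlation between genes 0 of the 28 passed, and the adjusted p = 0.952 for each of the 3. The list of collagens and extracellular matrix, which holds structural proteins laid down around the cells, rose by 0.32 on the log2 scale ± 0.15 (SD, n = 4; adjusted p = 5.24e-06, but adjusted p = 0.952 with an estimated correlation). The shift was positive on 4 of 4 arrays, from 0.19 to 0.50. Of its 56 measured members, 42 had a positive and 14 a negative ratio, 20 and 1 of them at an unadjusted p under 0.05. None passed over all genes tested, and 12 passed adjusted over the list alone, all of them higher. Lama2, the laminin chain of muscle basement membrane, was at 1.27 (SE 0.17, adjusted p = 0.0923). Col14a1, a collagen that binds fibril surfaces, was at 0.80, Hspg2, which encodes perlecan, at 0.77 and Efemp1, a fibulin, at 0.73. Fn1, fibronectin, was at 1.09 (SE 0.28, adjusted p = 0.140), though its 3 probes ran from -0.37 to 1.19, and Col3a1 was at 0.38, with 3 probes from -0.070 to 0.47. The list of matrix proteases and inhibitors rose by 0.30 ± 0.084 (SD, n = 4; adjusted p = 4.33e-05, but adjusted p = 0.952 with an estimated correlation), again on 4 of 4 arrays, and 24 of 30 members had a positive ratio. In it 7 genes passed adjusted over the list alone and 0 over all genes. Its examples were Adam17, the sheddase of tumour necrosis factor, at 0.95 (SE 0.11), Adam9 at 0.69, the serine protease inhibitor Serpine2 at 0.63 and the lysosomal protease Ctsb at 0.61. The unadjusted p with an estimated correlation was 0.107 for collagens and 0.0417 for proteases. Within the 3 arrays of slide 1 the shifts were 0.30 (adjusted p = 0.00143) and 0.28 (adjusted p = 0.00287). The array of slide 2 alone, which has no test, gave 0.38 and 0.37, and over the alternatives with camera's preset correlation the adjusted p stayed between 8.43e-11 and 0.00448 for collagens and between 3.49e-06 and 0.00448 for proteases.

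The list of cell cycle and DNA replication genes rose by 0.19 ± 0.19 (SD, n = 4; adjusted p = 5.24e-06 by camera, but adjusted p = 0.952 with an estimated correlation), and it was positive on 3 of 4 arrays. Of 82 members, 60 had a positive and 22 a negative ratio, 5 passed adjusted over the list alone, all higher, and 0 passed over all genes. Pbk, a mitotic kinase, was at 0.69 (SE 0.091), Top2a, the topoisomerase of dividing cells, at 0.59, with another probe at 0.15, the chromosome-associated kinesin Kif4 at 0.53 and the spindle assembly factor Tpx2 at 0.49. Replicate 4 had the highest shift, 0.44, and without it the call was lost: within slide 1 the shift was 0.11 (adjusted p = 0.182, the highest of the alternatives, with 2.77e-08 the lowest). The unadjusted p with an estimated correlation was 0.262. Fry gave an unadjusted p of 0.154 for the cell cycle list (adjusted p = 0.606).

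**Figure D1:**
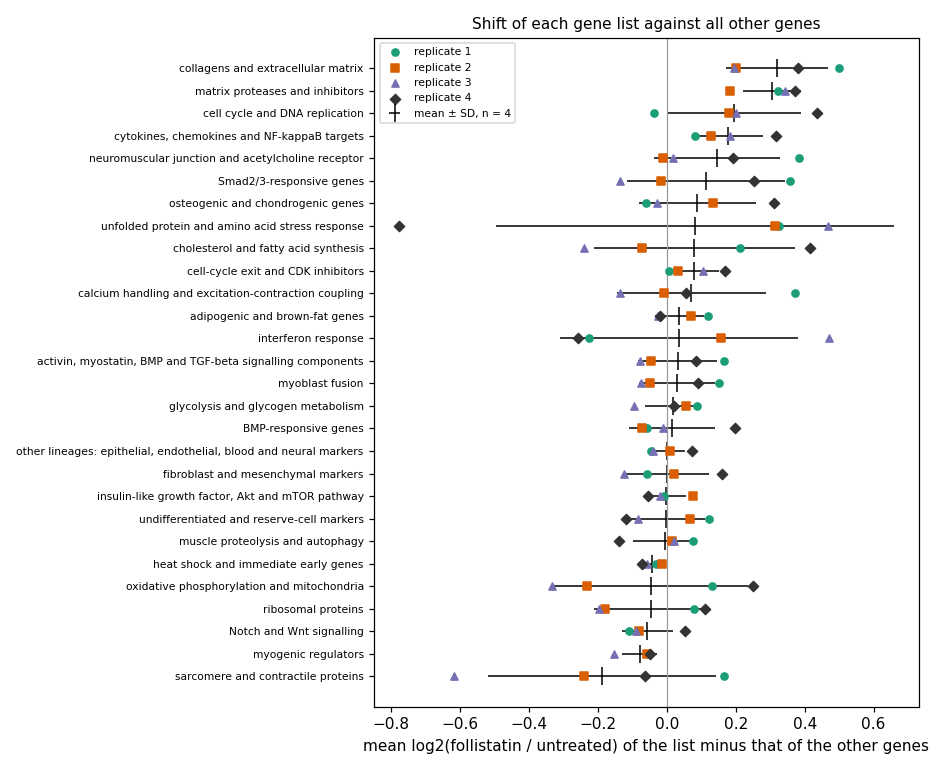
Shift of each of the 28 gene lists, as the mean log2 ratio of follistatin over untreated of its members minus that of all other genes, on the horizontal axis, with 1 symbol per array and a bar for the mean ± SD (n = 4). Collagens and matrix proteases lay above 0 on all 4 arrays, while the unfolded protein list was at -0.78 on replicate 4 and between 0.31 and 0.47 on the other arrays.

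The list of sarcomere and contractile proteins, the machinery of differentiated myotubes, did not pass the test: its shift was -0.19 ± 0.33 (SD, n = 4; adjusted p = 0.0923 by camera). Of 55 members, 37 had a negative and 18 a positive ratio, 3 passed adjusted over the list alone, all lower, and 0 passed over all genes. Tnnc2, fast skeletal troponin C, was at -1.07 (SE 0.15, adjusted p = 0.0937). The fast myosin heavy chain Myh4 was at -0.62, with another probe at -0.41, the perinatal chain Myh8 at -0.55, with 3 probes from -0.55 to 0.15, and the M-band protein Myom2 at -0.39, and all 4 genes were negative on 4 of 4 arrays. They were the 4 members of smallest p, a choice that favours agreement over arrays, and 11 of all 55 members were negative on 4 of 4. Another 3 muscle products split by array: creatine kinase Ckm was at 1.01 on replicate 1 and between -1.19 and -0.77 on the others, skeletal actin Acta1 at 0.82 against -0.77 to -0.45, and embryonic myosin Myh3 at 0.35 against -1.30 to -0.70. Without replicate 1 the list fell by 0.31 on the log2 scale (adjusted p = 4.00e-04), and with median centring in place of loess it fell by 0.27 (adjusted p = 0.00291). The shift of sarcomere and contractile proteins was -0.046 without replicate 3 (adjusted p = 0.649) and 0.050 with replicates 1 and 4 alone (adjusted p = 0.661), the latter a fit chosen after seeing the data. It passed in 6 of the 22 alternatives that test lists with camera at its preset correlation, with adjusted p from 4.00e-04 to 0.661. On all 4 arrays the adjusted p = 0.952 with an estimated correlation, from an unadjusted p of 0.567. The array of slide 2 alone gave -0.064.

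The myogenic regulators, 17 of them measured, had a shift of -0.079 ± 0.051 (SD, n = 4; adjusted p = 0.861). Myog, which drives terminal differentiation, was at -0.39 (SE 0.10, adjusted p = 0.150) and negative on 4 of 4 arrays. Myod1 was at 0.065, Myf5 at 0.34, Myf6 at 0.18 and Mef2c at -0.98 (SE 0.37, adjusted p = 0.235). Myf5 was at -1.02 on replicate 4 and between 0.30 and 1.12 on the others, and Mef2c ran from -2.22 on replicate 3 to 0.12 on replicate 4. The fusion factor Mymk was at -0.21 ± 0.90 (SD, n = 4), and the list of myoblast fusion genes was at 0.029 ± 0.11.

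Components of the activin, myostatin, BMP and TGF-beta pathways, which follistatin's ligands use, had a shift of 0.031 ± 0.11 (SD, n = 4; adjusted p = 0.861), with 23 members positive and 23 negative. The Smad2/3-responsive genes were at 0.11 ± 0.23 (adjusted p = 0.709) and the BMP-responsive genes at 0.014 ± 0.13 (adjusted p = 0.878). The transcript of follistatin itself, Fst, was at -0.59 (SE 0.37, adjusted p = 0.421), from -1.58 on replicate 3 to 0.73 on replicate 4. Inhba, the activin A subunit, was at -0.50 (SE 0.15, adjusted p = 0.173) and the inhibitory Smad7 at -0.42 (SE 0.13, adjusted p = 0.173), both negative on 4 of 4 arrays. Id1, a BMP target, was at -0.75 (SE 0.26, adjusted p = 0.216), negative on replicates 1, 2 and 3 and at 0.24 on replicate 4, and Id3 was at 0.0062, or -0.018 with the processed signals. The receptor Acvr2b was at -0.12, the receptor Acvr1 at 0.31, Smad4 at -0.35 and Fstl1 at 0.56. The probe for Mstn, myostatin, was not well above background in either channel on any array and was not tested. Igf1 was at -0.38 ± 0.92, with 4 probes from -0.38 to -0.011, and Igf2 at -0.27 ± 0.43 (SD, n = 4), Cdkn1a at 0.11 ± 0.84, and the muscle ubiquitin ligases Fbxo32 at -0.15 ± 0.28, with another probe at -0.034, and Trim63 at -0.025 ± 0.58, or 0.043 with median centring. Of the commonly used reference transcripts, Gapdh was at 0.020 ± 0.89, with 1.31 on replicate 1 and -0.66 to -0.13 on the others, and it was at -0.10 with median centring in place of loess and at -0.040 on its other probe. Actb was at 0.56 ± 0.61.

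**Figure D2:**
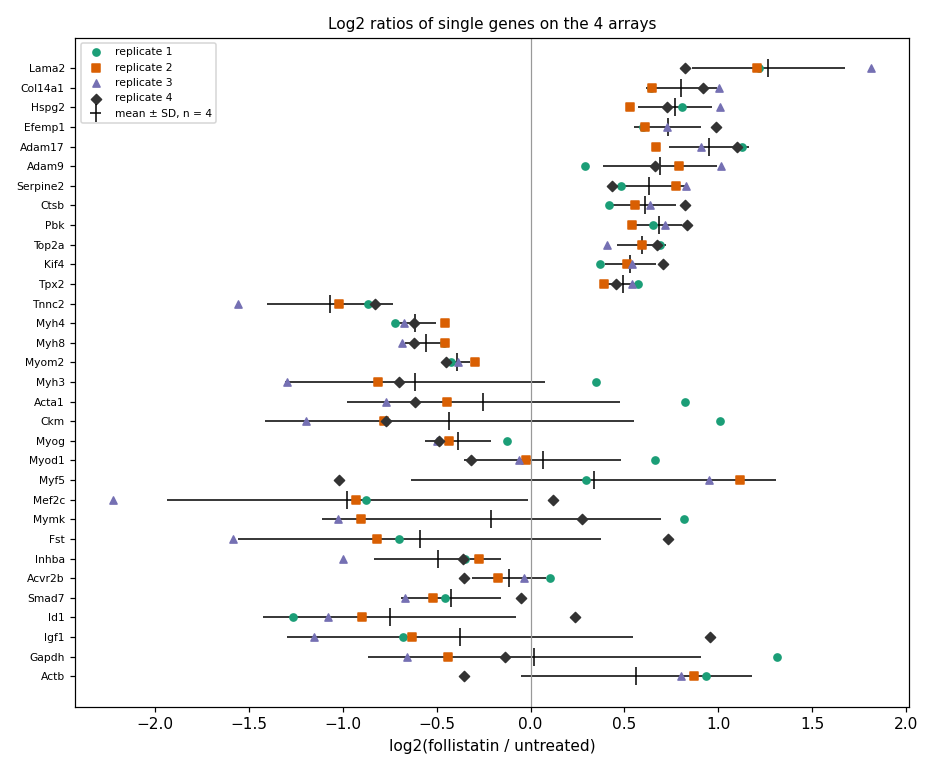
Log2 ratio of follistatin over untreated for 32 genes on the horizontal axis, with 1 symbol per array and a bar for the mean ± SD (n = 4). The matrix, protease and cell cycle genes at the top, the 4 members of smallest p of each list, were positive on all 4 arrays. That choice favours agreement over arrays. Over the whole lists, 22 of 56 collagen, 12 of 30 protease and 29 of 82 cell cycle members were positive on all 4 arrays. Ckm, Acta1 and Myh3, from a fixed set, were positive on replicate 1 alone.

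No other list passed the test. The cytokines, chemokines and NF-kappaB targets were at 0.18 ± 0.10 (SD, n = 4; adjusted p = 0.0923), positive on 4 of 4 arrays. It passed in 6 of the 22 alternatives with camera's preset correlation, at shifts of 0.17 to 0.28, with adjusted p over the alternatives from 0.00888 to 0.644. With an estimated correlation on all 4 arrays this list had an unadjusted p of 0.147 and an adjusted p = 0.952. Its member C3, the central complement component, was at 0.91 (SE 0.14) and the chemokine Cxcl5 at 1.22 (SE 0.38). Cholesterol and fatty acid synthesis was at 0.079 ± 0.29, the neuromuscular junction list at 0.15 ± 0.18, calcium handling at 0.071 ± 0.22, osteogenic and chondrogenic genes at 0.088 ± 0.17, and cell-cycle exit at 0.077 ± 0.074. The unfolded protein and amino acid stress response was at 0.081 ± 0.58 and the interferon response at 0.035 ± 0.35. Shifts lay at -0.057 ± 0.075 for Notch and Wnt signalling, -0.045 ± 0.027 for heat shock and immediate early genes, -0.047 ± 0.16 for ribosomal proteins and -0.047 ± 0.28 for oxidative phosphorylation. Adipogenic genes were at 0.035 ± 0.071, glycolysis at 0.016 ± 0.081, the insulin-like growth factor, Akt and mTOR pathway at -0.0022 ± 0.056, and muscle proteolysis and autophagy at -0.0066 ± 0.093. Undifferentiated and reserve-cell markers were at -0.0041 ± 0.12, fibroblast and mesenchymal markers at -0.0010 ± 0.12, and markers of other lineages (epithelial, endothelial, blood and neural) at -0.00087 ± 0.054. Under another scaling of the arrays the sign turned for glycolysis, the insulin-like growth factor list, muscle proteolysis, oxidative phosphorylation, ribosomal proteins and the reserve-cell, fibroblast and other-lineage markers. The sign of the mean shift differed from camera's direction for adipogenic genes, the insulin-like growth factor list, fibroblast markers and muscle proteolysis, and the median of the myoblast fusion genes was negative at -0.037. In these lists 0 genes passed over all genes tested. Adjusted over the list alone, 2 osteogenic genes were higher, as was 1 gene each of the cytokine, neuromuscular junction and interferon lists. Counted the same way, 1 ribosomal protein was higher and 3 lower, 1 reserve-cell marker higher and 2 lower, 2 fibroblast markers higher and 2 lower, and 1 proteolysis gene higher and 1 lower. The unfolded protein, cell-cycle exit and adipogenic lists each had 1 lower.

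Several of these lists passed by camera under some alternatives. With the reported processing on all 4 arrays none did, with adjusted p = 0.952 with an estimated correlation for each. The unfolded protein list was called in both directions: it rose by 0.37 within slide 1, that is without replicate 4 (adjusted p = 9.52e-05), and fell by 0.23 on the log2 scale with replicates 1 and 4 alone (adjusted p = 0.0127). Cholesterol and fatty acid synthesis rose by 0.18 without replicate 3 (adjusted p = 0.00901), by 0.16 with replicates 2 and 3 averaged (adjusted p = 0.0485) and by 0.31 with replicates 1 and 4 alone (adjusted p = 1.83e-05), while within slide 1 the shift of cholesterol and fatty acid synthesis was -0.034 (adjusted p = 0.986). With replicates 1 and 4 alone the Smad2/3-responsive genes also rose by 0.30 (adjusted p = 0.00177), the neuromuscular junction list by 0.29 (adjusted p = 0.0164) and oxidative phosphorylation by 0.19 (adjusted p = 3.75e-04), and the interferon response fell by 0.24 on the log2 scale (adjusted p = 0.00112). Both fits that average replicates 2 and 3 or leave them out were chosen after seeing the data. On all 4 arrays another 2 lists passed under other processing: ribosomal proteins fell by 0.21 on the log2 scale with median centring in place of loess (adjusted p = 0.00405), and calcium handling rose by 0.17 with every probe as its own feature (adjusted p = 0.0188). The highest adjusted p over the alternatives lay between 0.963 and 1.00 for each of these 8 lists.

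The spike-in transcripts, added to each RNA at set ratios, were measured by 10 probes. Their mean log2 ratio of Cy3 over Cy5 after normalization to the cellular transcripts was -1.07 on replicate 1, -2.33 on replicate 2, -2.59 on replicate 3 and -0.20 on replicate 4. Per the file headers, observed against expected spike-in log ratios had slopes of 0.886, 0.937, 0.909 and 0.888 and intercepts, as log10 of Cy5 over Cy3, of 0.356, 0.746, 0.825 and 0.0661.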

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

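No test in this part was chosen after the results were seen. The test for a single array far from the other 3 was applied to 94 results, each a named gene's ratio, a list's shift or the spike-in ratio on the 4 arrays. It marked 6, where chance marks about 1 in 20, or 4.7, with independent arrays. Independence was not shown for replicates 2 and 3. Part of the genes were also chosen by smallest p, which favours agreement over arrays, so that rate need not hold here. The unfolded protein and amino acid stress response was at -0.78 on replicate 4, on slide 2, and between 0.31 and 0.47 on the other arrays. Actb was at -0.35 on replicate 4 and between 0.80 and 0.93 on the others. C3 was at 0.48 on replicate 4 and between 1.01 and 1.11 on the others. Inhba was at -0.999 on replicate 3 and between -0.36 and -0.27 on the others. Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, was at -1.51 on replicate 3 and between -0.88 and -0.87 on the others. The myogenic regulators were at -0.15 on replicate 3 and between -0.058 and -0.048 on the others. No explanation was tested for these results.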

How the results depend on the processing

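The averaging of replicates 2 and 3, the fit of replicates 1 and 4 alone and the correction for base composition were tests chosen after the results were seen. The 26 alternatives held 22 that test lists with camera at its preset correlation. In these the collagen list passed 22 times, at shifts of 0.25 to 0.44, and the matrix proteases 22 times, at 0.26 to 0.45. The cell cycle list passed in 20 of 22, at 0.11 to 0.34. The 22 were not all separate checks: Aquantile normalization between arrays repeated the reported list results, and the authors' table nearly repeated the processed signals. Slide 1 alone and leaving out replicate 4 were the same fit, and the cell cycle list was lost there alone. With an estimated correlation on all 4 arrays 0 lists passed. Of 1689 values for single genes, 1597 kept their direction and side of the threshold, 62 newly passed and 30 turned sign. Of 728 list shifts, 618 counted as unchanged, 21 newly passed, 2 no longer passed and 87 turned sign. Unchanged meant the same direction and side of the threshold. Where camera was not run, it meant the same direction and a shift within the SD over the arrays of the reported one. Where the count of genes past the threshold left 0, the processed signals and the authors' table each gave 2 genes, 2 of them lower and 2 over 1.6-fold. These were Ces3b, at -3.23 against -0.54 with the reported processing, and Olfr1299, at -2.92 against -0.29, named after their values were seen. Array weights gave 2751 genes, 1138 higher, 1613 lower and 1116 over 1.6-fold, with weights of 0.534, 2.46, 1.64 and 0.464 that favour replicates 2 and 3. Separate channels without the array gave 26 genes, 14 higher, 12 lower and 24 over 1.6-fold. A random array effect, with an estimated correlation within a spot of -0.00714, gave 24, 13 higher, 11 lower and 22 over 1.6-fold. The count of lists was 6 with median centring, 5 with every probe apart, 5 with replicates 2 and 3 averaged, 10 with replicates 1 and 4 alone, 0 with an estimated correlation and 0 with fry. Without each replicate in turn, it ran from 3 to 5, and the count of genes was 0 each time by limma, with 1741 to 4625 at an unadjusted p under 0.05. Camera was not run for the slide block, the random array effect, the methods' t-test or trended variances. Signal over background limits the dim genes, whose ratios are compressed. The cause of the following turns was not tested. With processed signals the sign turned for the log2 ratio of Id3 (-0.018), the shift of insulin-like growth factor, Akt and mTOR pathway (0.033), the shift of muscle proteolysis and autophagy (0.014), the shift of oxidative phosphorylation and mitochondria (0.0018), the shift of undifferentiated and reserve-cell markers (0.030), the shift of fibroblast and mesenchymal markers (0.11) and the shift of ribosomal proteins (0.036). With an offset of 16 the sign turned for the shift of insulin-like growth factor, Akt and mTOR pathway (0.0048), the shift of fibroblast and mesenchymal markers (0.026) and the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0027). With no background subtraction the sign turned for the shift of insulin-like growth factor, Akt and mTOR pathway (0.0028) and the shift of fibroblast and mesenchymal markers (0.011). With median centring the sign turned for the log2 ratio of Trim63 (0.043), the log2 ratio of Gapdh (-0.10), the shift of glycolysis and glycogen metabolism (-0.024) and the shift of undifferentiated and reserve-cell markers (0.011). With scaling between arrays the sign turned for the shift of fibroblast and mesenchymal markers (0.0068) and the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0019). With the authors' table the sign turned for the log2 ratio of Id3 (-0.018), the shift of insulin-like growth factor, Akt and mTOR pathway (0.030), the shift of muscle proteolysis and autophagy (0.014), the shift of oxidative phosphorylation and mitochondria (0.011), the shift of undifferentiated and reserve-cell markers (0.030), the shift of fibroblast and mesenchymal markers (0.11) and the shift of ribosomal proteins (0.036). With no dim filter the sign turned for the shift of BMP-responsive genes (-0.00089) and the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0064). With the variation filter the sign turned for the shift of muscle proteolysis and autophagy (0.020). With every probe apart the sign turned for the shift of neuromuscular junction and acetylcholine receptor (-0.036), the shift of BMP-responsive genes (-0.057), the shift of cell-cycle exit and CDK inhibitors (-0.0037), the shift of other lineages: epithelial, endothelial, blood and neural markers (0.013) and the shift of ribosomal proteins (0.011). With the mean of a gene's probes the sign turned for the log2 ratio of Gapdh (-0.0099), the shift of activin, myostatin, BMP and TGF-beta signalling components (-0.0030), the shift of insulin-like growth factor, Akt and mTOR pathway (0.021), the shift of glycolysis and glycogen metabolism (-0.0058), the shift of undifferentiated and reserve-cell markers (0.038), the shift of fibroblast and mesenchymal markers (0.045), the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0014) and the shift of ribosomal proteins (0.0056). With the slide block the sign turned for the shift of fibroblast and mesenchymal markers (0.0076) and the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0030). With slide 1 alone the sign turned for the log2 ratio of Id3 (-0.18), the log2 ratio of Cdkn1a (-0.11), the shift of BMP-responsive genes (-0.047), the shift of insulin-like growth factor, Akt and mTOR pathway (0.016), the shift of muscle proteolysis and autophagy (0.038), the shift of cholesterol and fatty acid synthesis (-0.034) and the shift of undifferentiated and reserve-cell markers (0.034). With array weights the sign turned for the log2 ratio of Id3 (-0.25), the log2 ratio of Cdkn1a (-0.32), the log2 ratio of Gapdh (-0.30), the shift of calcium handling and excitation-contraction coupling (-0.0042), the shift of myoblast fusion (-0.024), the shift of activin, myostatin, BMP and TGF-beta signalling components (-0.023), the shift of BMP-responsive genes (-0.026), the shift of insulin-like growth factor, Akt and mTOR pathway (0.024), the shift of muscle proteolysis and autophagy (0.0094), the shift of cholesterol and fatty acid synthesis (-0.052) and the shift of undifferentiated and reserve-cell markers (0.0064). With replicates 2 and 3 averaged the sign turned for the log2 ratio of Mymk (0.043), the log2 ratio of Trim63 (0.13), the shift of oxidative phosphorylation and mitochondria (0.032), the shift of interferon response (-0.057), the shift of unfolded protein and amino acid stress response (-0.021), the shift of fibroblast and mesenchymal markers (0.016) and the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0038). With replicates 1 and 4 alone the sign turned for the log2 ratio of Fst (0.016), the log2 ratio of Myf5 (-0.36), the log2 ratio of Acta1 (0.11), the log2 ratio of Ckm (0.12), the log2 ratio of Mymk (0.55), the log2 ratio of Igf1 (0.14), the log2 ratio of Trim63 (0.44), the shift of sarcomere and contractile proteins (0.050), the shift of oxidative phosphorylation and mitochondria (0.19), the shift of interferon response (-0.24), the shift of unfolded protein and amino acid stress response (-0.23), the shift of undifferentiated and reserve-cell markers (0.0012), the shift of fibroblast and mesenchymal markers (0.051), the shift of other lineages: epithelial, endothelial, blood and neural markers (0.013) and the shift of ribosomal proteins (0.094). With the base composition correction the sign turned for the log2 ratio of Trim63 (0.0030), the shift of undifferentiated and reserve-cell markers (0.029), the shift of fibroblast and mesenchymal markers (0.016) and the shift of other lineages: epithelial, endothelial, blood and neural markers (0.0040). Leaving out each replicate turned the sign of these, with their ranges: the log2 ratio of Id3 -0.18 to 0.20, the log2 ratio of Myod1 -0.13 to 0.19, the log2 ratio of Cdkn1a -0.16 to 0.37, the log2 ratio of Gapdh -0.41 to 0.25, the shift of calcium handling and excitation-contraction coupling -0.030 to 0.13, the shift of myoblast fusion -0.012 to 0.064, the shift of activin, myostatin, BMP and TGF-beta signalling components -0.014 to 0.068, the shift of glycolysis and glycogen metabolism -0.0074 to 0.054, the shift of fibroblast and mesenchymal markers -0.055 to 0.040, the shift of other lineages: epithelial, endothelial, blood and neural markers -0.025 to 0.014, the log2 ratio of Mymk -0.55 to 0.063, the log2 ratio of Trim63 -0.24 to 0.19, the shift of oxidative phosphorylation and mitochondria -0.15 to 0.055, the shift of interferon response -0.11 to 0.13, the shift of unfolded protein and amino acid stress response -0.047 to 0.37, the shift of undifferentiated and reserve-cell markers -0.046 to 0.034, the shift of ribosomal proteins -0.10 to 0.0030, the shift of BMP-responsive genes -0.047 to 0.043, the shift of insulin-like growth factor, Akt and mTOR pathway -0.028 to 0.016, the shift of muscle proteolysis and autophagy -0.034 to 0.038 and the shift of cholesterol and fatty acid synthesis -0.034 to 0.18.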

Other observations

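The tests of the slide, the normalization, single arrays, the second probes of collagen genes, the opposite dye orientation, the sign assignments for single genes, the averaging of replicates 2 and 3, the fit of replicates 1 and 4 alone, and the correction for base composition were chosen after the results were seen. Genes of 1 sign on all 4 arrays were no more frequent in the insulin-like growth factor, Akt and mTOR list (5 higher and 5 lower of 38) or in the Notch and Wnt list (2 higher and 7 lower of 45) than over all features, 28.0%. No gene in them passed over all genes tested. In the insulin-like growth factor, Akt and mTOR list, whose shift was near 0, 4 genes passed adjusted over the list alone, 1 higher and 3 lower. Among them Pdpk1, the kinase that activates Akt, was at -1.21 (SE 0.16), with 3 probes from -1.21 to -0.49, and Pik3r1 at -1.03 (SE 0.14), with 4 probes from -1.03 to -0.18. In the Notch and Wnt list 1 gene higher and 4 lower passed adjusted over the list alone, among them the Wnt effectors Lef1 at -0.96 (SE 0.18), with another probe at -0.28, and Tcf7l2 at -0.99 (SE 0.21), with 4 probes from -0.99 to -0.0065. Over the 12 Notch and Wnt genes with a second bright probe the shift was -0.19 on the brightest probes and 0.019 on the second. The glucose transporter Slc2a1 was at -0.80 (SE 0.099) and the glycolytic enzyme Aldoa at -0.63 (SE 0.11), with another probe at -0.25, and these were the 2 members of the glycolysis list that passed adjusted over it alone. Trim55, a ubiquitin ligase of the sarcomere, was at -1.23 (SE 0.16), and Phex, an endopeptidase of mineralising tissue, at 1.02 (SE 0.14).

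More genes had an unadjusted p under 0.05 than chance gives with independent arrays, 3478 against 893, although 0 passed limma's adjusted threshold, and there were 2019 with replicates 2 and 3 averaged and 1301 with replicates 1 and 4 alone. The 8 sign assignments of the arrays are too few for a share under 0.05: the real one gave 3478 and the highest other 2640, with 1 assignment as large. Assignments that turned only 1 of replicates 2 and 3 set this correlated pair (r = 0.84) against itself. They gave 303, 65, 40 and 159 genes at that unadjusted p, so the 8 assignments are not alike. Past the adjusted threshold 8 of 8 gave 0 genes (highest other 0). At least the real 3 lists came from 6 of 8, the real one included, so other assignments matched the number of list calls. Which lists these were was not recorded. The highest other count was 14, with replicate 3 turned, which points to a structure of the arrays whose nature was not tested. Correction for base composition and intensity, which explained 2.09% of the variance of the mean ratio, left 3642 genes and argues against a dye effect set by these as the whole cause. Over 5495 genes with 2 bright probes, the mean ratios of the probes correlated at r = 0.26 and their array-specific deviations, which a constant dye effect cannot make, at r = 0.33, a quotient of 0.765 that lies between the bounds set beforehand, so a dye effect specific to single probes may account for part of the excess. A dye effect shared by all probes of a transcript cannot be told apart from follistatin, since 0 arrays had the opposite dye orientation per the labels.

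Replicates 2 and 3 shared deviations that the other arrays lacked, with r = 0.84 between them across genes. A shared slide and scan is argued against as the whole cause, because replicate 1, on the same slide, correlated with them at no more than r = 0.234 (rho = 0.312). The normalization is argued against as well: the lowest correlation of the pair, with median centring, was 0.789. These 2 arrays also had the lowest spike-in ratios. It stays open, as untested, whether the cultures differed or whether replicates 2 and 3 may come from the same cultures or RNA, which would make them 1 biological replicate and n = 3 for every SE, SD and p.

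The higher ratios of collagens and matrix proteases with follistatin were weighed on the collagen list. Its shift was 0.32, and 0.308 after correction for base composition and intensity, so this dye trend is argued against as the whole cause. The lowest shift with 1 array left out was 0.258, so no single array made it. In the 21 members with a second bright probe, 37.5% of those tested and too few to decide, the second probes had a shift of 0.232 and the brightest 0.264. Several explanations stay open: genes that vary together between cultures, since the list did not pass with an estimated correlation (unadjusted p = 0.107, adjusted p = 0.952), a dye effect shared by all probes of these transcripts, and a response to follistatin, which may be kept only as a hypothesis. The sign assignments, of which 6 of 8 with the real one included gave at least as many lists, did not record which lists passed. They therefore do not bear on the collagen list by itself.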
